A study of Homo sapiens with 5 samples.

How the data were processed

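Total RNA of MCF7 cells, untreated or in 1 µM RITA for 2, 8, 16 or 24 h, had been labelled with biotin and hybridized to single-colour Affymetrix oligonucleotide arrays, 1 array per sample and no pooling, per the labels. The deposited values are signal intensities on a linear scale, 1 per probe set and array. From the values, the authors had scaled each array to a common trimmed mean (2% trimmed at each end; 200.07 to 200.11 over the 5 arrays). The submitters' processing notes name the software GCOS 1.4 without its options, and detection calls were not used here.

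Of 22277 probe sets, 19070 were listed with 1 gene, 1043 with several and 2164 with none; the last 2 kinds were left out of gene results. Symbols came from the deposited array table, and 19058 of the gene identifiers matched a reference gene table that served for names only. Genome coordinates were not used here. TP53, CASP3, BBC3 and PIK3CA had no probe set listed with them alone and were not analysed here. A gene took the value of its probe set with the highest mean log2 signal over the 5 arrays, which gave 11963 genes, 6708 of them with mean signal above the floor. The floor was the median of all probe-set signals, 31.4. No values were rescaled, since the trimmed means differed by less than 10%, and no pseudocount was added. Probe sets whose names end in _x_at (2428, or 10.9%) can match several sequences by the manufacturer's design.

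Each treated array was compared with the untreated one by size. Genes that crossed the floor were counted apart, where the higher signal lay at least 2-fold above it. A gene counted as higher or lower at 2-fold or more with both signals above the floor. Genes past this rule in one direction at 8, 16 and 24 h counted as sustained. Agreement was also taken between comparisons that share no array. What the shared untreated array gives by itself was simulated in 100 sets of unchanged arrays, with noise drawn from the spread between the 2 h and untreated arrays in 20 signal groups. The time trend was the slope on hours by limma 3.58.1 (lmFit, eBayes with an intensity trend, 3 residual degrees of freedom) in R 4.3.3, over genes with mean signal above the floor, with Benjamini-Hochberg adjustment at 0.05. Departures from a straight line are its error. The label of the untreated array gives no time, and it was taken as 0 h.

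The 24 gene lists were p53 targets, pro-apoptotic genes, survival and growth signalling, S phase, G2/M, estrogen response, luminal identity, integrated stress and unfolded protein responses, oxidative stress, heat shock, immediate-early genes, NF-κB, interferon response, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, DNA repair, histones, matrix and mesenchymal genes, blood cell markers, proteasome and zinc finger genes. Lists, comparisons, tests and alternatives were fixed before the data were examined, except where said. A list needed 5 genes above the floor. Its median difference was placed among 10000 random lists of its size matched on mean signal in 10 groups, and limma's camera tested its slope against other genes with a preset correlation of 0.01, with an estimated correlation and fry beside it. With an estimated correlation camera rests on the 3 residual degrees of freedom, which leaves it little power. Genes named are the 10 highest and 10 lowest at each time, the 10 of largest least difference per direction over 8, 16 and 24 h, the 10 of lowest adjusted p per direction in the trend, up to 4 members per list with the largest mean difference over 8, 16 and 24 h, and any member of the p53, pro-apoptotic and survival lists.

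Alternatives tried were arrays shifted to a common median, quantile normalization, scaling on the 100 normalization-control probe sets, floors at percentiles 30 and 70 or none, the median of a gene's probe sets, only plain _at probe sets, a pseudocount at percentile 20 of the signals (4.2), rules of 1.5-fold and 3-fold, and the 2 h array as baseline. For the trend they were log2(hours + 1), rank of time, each array left out in turn and eBayes without an intensity trend, and for the lists also unmatched random lists. Scaling on the 18 probe sets of the hybridization controls and leaving out _x_at probe sets were chosen after the data were seen. The methods were tested on simulated data: of 200 changed genes among 6708, the trend recovered 0% at a log2 change of 1, 70.0% at 2 and 96.5% at 4, and the size rule recovered 5% of 200 among 11963 at a log2 difference of 0.5 and 97.5% at 1.5. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.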

Results

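MCF7 is an estrogen-receptor-positive human breast carcinoma cell line. RITA is a small molecule that activates the tumour suppressor p53, a transcription factor that induces cell cycle arrest and apoptosis. MCF7 cultures were either left untreated or given 1 µM RITA for 2, 8, 16 or 24 h, and total RNA of each was hybridized to 1 single-colour oligonucleotide array, 5 arrays in all. Each array gave a signal intensity for 22277 probe sets, which named 11963 genes. The arrays shared one trimmed mean signal, between 200.07 and 200.11, and their median signals were 35.6 untreated, 33.7 at 2 h, 30.6 at 8 h, 29.0 at 16 h and 29.9 at 24 h. Between 48.7% and 51.7% of the probe sets on an array lay above a signal floor of 31.4. With 1 array per group there was no replicate error, so differences from untreated cells were counted by size, at least 2-fold with both signals above the floor, and the number of arrays limits their precision. No vehicle-treated or time-matched untreated culture is among the samples. An effect of RITA therefore cannot be told apart from one of solvent or of hours in culture. The single test was a straight-line trend over the 5 arrays, and below "rose" and "fell" are used only of genes or lists that passed it.

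The array-wide controls changed over the course and set a limit on every direction given here. Bacterial transcripts added at hybridization were 1.13 log2 units higher at 24 h than untreated, and the poly-A transcripts added to the RNA before labelling were 2.04 units higher. On the deposited scale the median of the 6708 genes with mean signal above the floor was -0.25 log2 units from untreated at 24 h. It was 0.01 after quantile normalization, -0.62 after scaling on the 100 normalization-control probe sets and -1.39 after scaling on the hybridization controls, the last of these scalings being chosen after the data were seen, so gene lists are described relative to the median of all genes. The difference also depended on brightness: the brightest of 20 equal signal groups had a median of 0.73 at 24 h, the next 0.31 and the dimmest -0.46.

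**Figure D1:**
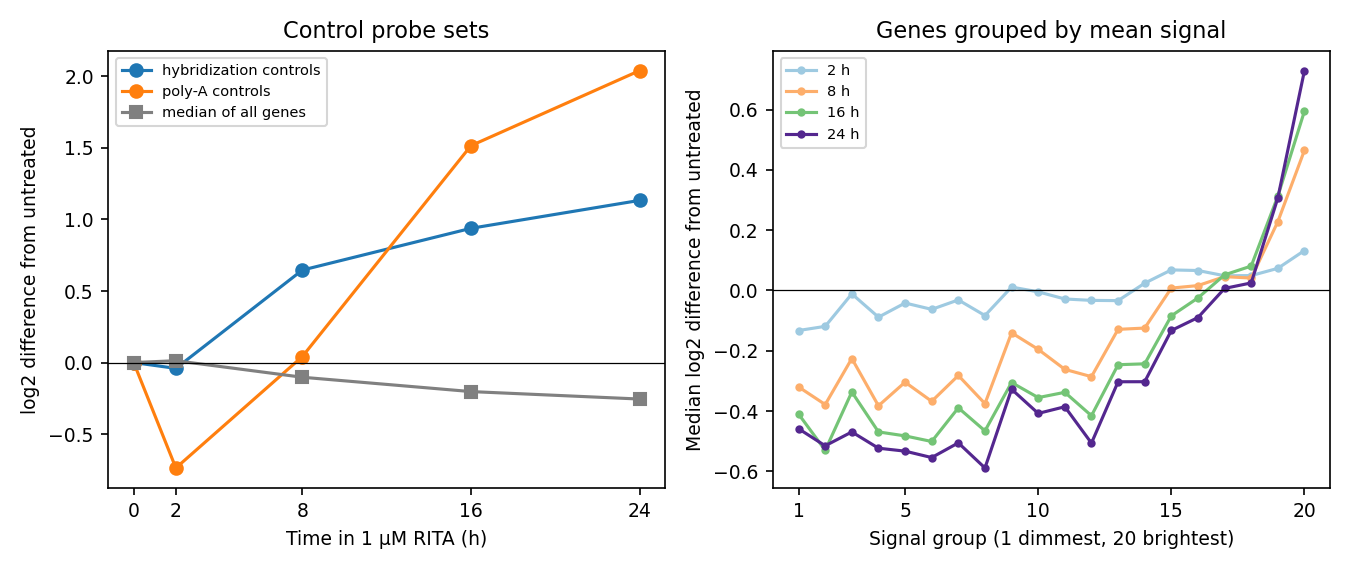
Left, mean log2 difference from untreated (vertical axis) of the hybridization controls, the poly-A controls and the median gene against hours in 1 µM RITA; both controls lay above 0 at 16 and 24 h. Right, median log2 difference from untreated of 20 signal groups of genes, dimmest to brightest, with 1 line per time and the brightest group highest at each.

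The 2 h array addressed the earliest transcript response. The fixed p53 list described further on lay 0.05 log2 units above all genes at 2 h (percentile 76.4), with 4 of 29 members at least 2-fold higher and 1 lower. Furthest above untreated was GADD45A, a p53 target that acts in growth arrest and DNA repair, at 5.99-fold (signal 65.7 to 394), and PMAIP1, which encodes the pro-apoptotic BH3-only protein NOXA, was 5.55-fold higher (47.3 to 262). The G-protein regulator RGS2 (4.52-fold), the stress-induced transcription factor ATF3 (4.33-fold), IER5 (4.30-fold, 446 to 1919) and JUN (4.11-fold) followed, then ATF6, LTBP4, SH3BP2 and PAQR6 at 1.86, 1.72, 1.44 and 1.25 log2 units. Some other probe sets of LTBP4 and SH3BP2, each below the floor, had the opposite sign, as did a second probe set of ATF6 (55.6 to 28.2). Growth-factor-responsive EGR1 was 5.92-fold lower (588 to 99.3) and FOS 3.60-fold lower (295 to 81.8). The remaining 8 of the 10 lowest were KIAA0232 at -2.05 log2 units, the histone methyltransferase SETD1B at -1.67, ZNF85 at -1.64, the KIT ligand gene KITLG at -1.56, NPAT and USP6NL at -1.54 and -1.54, ARID4B at -1.53 and RNF111 at -1.46. ARID4B has a second probe set, below the floor, with the opposite sign. In all, 41 genes were at least 2-fold higher and 88 at least 2-fold lower among 6693 with both signals above the floor. Simulated unchanged arrays with the spread seen between these 2 arrays gave means of 22.5 and 23.6, so part of the 2 h count may be noise. That spread also holds any true difference at 2 h, so how large a part cannot be told. The split depended on scaling: it was 46 higher to 58 lower at a common median, 43 to 58 after quantile normalization, 35 to 129 on the normalization-control probe sets and 62 to 99 on the hybridization controls.

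The 8 h array addressed which of these differences lasted and which appeared later. PMAIP1, GADD45A and ATF3 were further from untreated than at 2 h: PMAIP1 stood 4.32 log2 units above untreated (signal 945), GADD45A 17.5-fold (1150.2) and ATF3 16.2-fold (523). GDF15, a secreted growth factor and p53 target, was 6.12-fold higher and MDM2, which encodes the ubiquitin ligase that degrades p53, 3.49-fold higher. Both values come from probe sets of a type that can match several sequences. The other probe set of GDF15 lay below the floor throughout (7.0 untreated, 1.7 at 8 h), and of the 4 others of MDM2, with untreated signals from 10.8 to 40.8, 2 were higher at 8 h and 2 lower. PPDPF (4.94-fold), PABPN1 (4.75-fold), IER5 (4.12-fold), METRN (4.06-fold) and VASP (3.51-fold) completed the 10 highest. The growth-promoting transcription factor MYC was 7.63-fold lower (2189.5 to 287) after little difference at 2 h (-0.28 log2 units). The RNA-binding protein gene PUM2 stood at 56.9 after 635 untreated, the chromatin gene CDYL at 53.3 after 585, and EGR1 was 9.44-fold lower. FBXO34, CHST15, SEC24B, E2F6, TBC1D30 and RSBN1 lay between -3.42 and -2.82 log2 units. Of 6446 genes, 179 were at least 2-fold higher and 748 lower. A further 24 crossed the floor upward and 153 downward, with the higher signal at least 2-fold above it. The split of 179 to 748 depended on scaling: it was 368 to 489 at a common median, 337 to 491 after quantile normalization, 72 to 1264 on the normalization-control probe sets and 17 to 2265 on the hybridization controls. Against the 2 h array in place of the untreated one, 48 genes were higher and 371 lower. Of the 41 genes higher at 2 h, 29 were also higher at 8 h, where independent lists would share 1.15. Of the 61 lower at 2 h and above the floor throughout, 50 were also lower, against 7.14 for independent lists. Part of both overlaps may come from the shared untreated array.

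The 16 h array extended the course towards late effects, and ATF3 (17.3-fold), PMAIP1 (16.3-fold), GADD45A (15.6-fold) and GDF15 (4.96-fold) were still among the 10 genes furthest above untreated on it. The other 6 entered the 10 highest at this time: NACA4P (1059 at 8 h to 9897), ZNF160 (299 to 2302), ZNF721 (618 to 3067), SLC35E1 (377 to 1610.5), the flippase gene ATP8B1 (104 to 622) and HAUS2 (252 to 631). All 6 are read by probe sets of the type that can match several sequences, and SLC35E1 was lower than untreated by its other probe sets. On the same array the 18S ribosomal RNA control went from 122 untreated to 6854 by its 3′ probe set, from 113 to 372 by its 5′ and from 76.9 to 349 by its middle one. The chromatin remodeller CHD1 was 12.5-fold lower, the endoplasmic reticulum stress kinase gene EIF2AK3 9.64-fold, the transcription factor gene ADNP 9.57-fold (1115 to 116) and the amino acid transporter gene SLC38A2 8.95-fold (1271 to 142). CDYL, PUM2, CHST15, MYC, DYRK1A and EGR1 were the other members of the 10 lowest, DYRK1A with other probe sets, all below the floor, that gave both signs. Of 6348 genes, 208 were at least 2-fold higher and 982 lower, with 26 crossing the floor upward and 196 downward on the same terms. The split was 539 to 593 at a common median, 403 to 569 after quantile normalization, 75 to 1639 on the normalization-control probe sets and 19 to 3305 on the hybridization controls, and 109 genes were higher when the 2 h array served as baseline.

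At 24 h, the end of the course, PMAIP1 was 23.1-fold higher than untreated (signal 1094), GADD45A 20.1-fold (1321), ATF3 18.6-fold (598) and MDM2 7.40-fold by its brightest probe set. NACA4P, ZNF160, SLC35E1, ZNF721, HAUS2 and ATP8B1 were again higher, between 2.99 and 4.68 log2 units. EGR1 was 18.6-fold lower and MYC at a signal of 146, -3.90 log2 units from untreated. Also lowest were PUM2 at -3.60 log2 units, CDYL at -3.43, DYRK1A at -3.39, ADNP at -3.22, the cyclin-dependent kinase gene CDK17 at -3.41, the nuclear pore gene NUP153 at -3.38 and GRHL2, an epithelial transcription factor gene, at -3.28. LEMD3, a gene of the inner nuclear membrane, was at -3.51 after values below the floor at 8 and 16 h. Of 6308 genes, 317 were at least 2-fold higher and 1182 lower, and 43 crossed the floor upward and 243 downward on the same terms. The split was 648 to 843 at a common median, 523 to 720 after quantile normalization, 115 to 1917 on the normalization-control probe sets and 29 to 3719 on the hybridization controls, and 185 genes were higher when the 2 h array served as baseline. Where a gene past the rule had another probe set above the floor, that probe set had the same sign for 68 of 86 genes called higher and 370 of 393 called lower. It also passed 2-fold for only 28 of the 86 and 228 of the 393. At 16 h the sign matched for 47 of 64 genes called higher and 289 of 299 called lower.

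**Figure D2:**
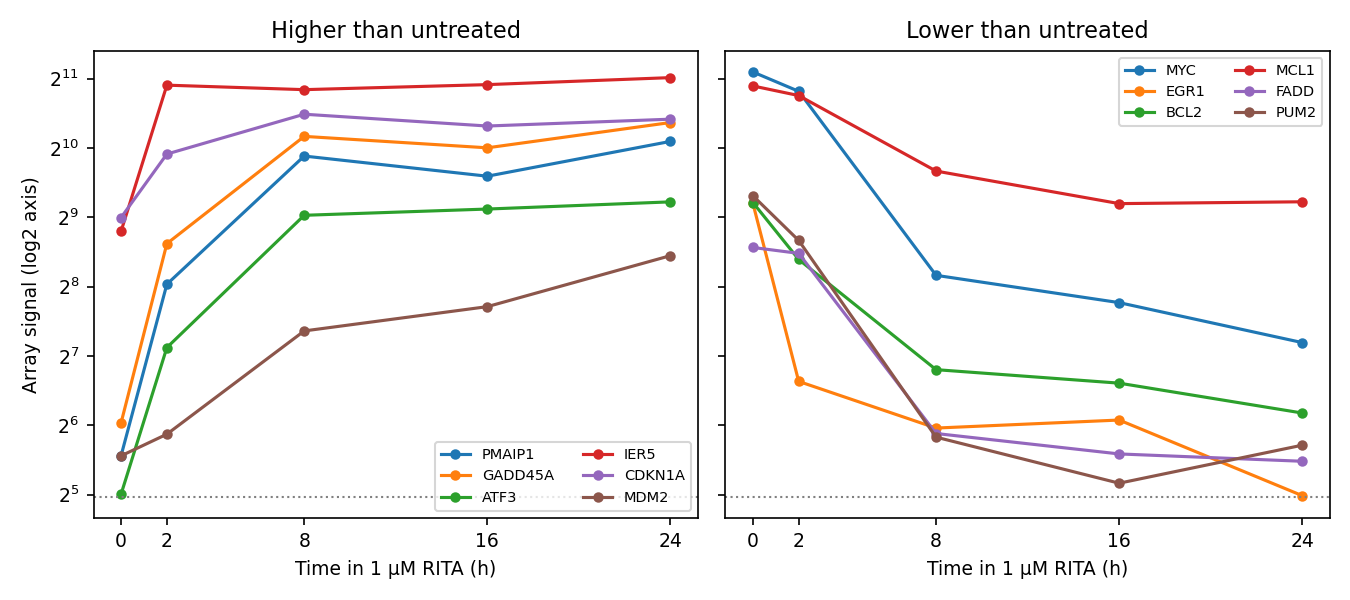
Array signal (vertical axis, log2 scale) against hours in 1 µM RITA for 6 genes higher and 6 genes lower than untreated, 1 array per point, with the signal floor of 31.4 dotted. PMAIP1, GADD45A, ATF3 and IER5 already stood above untreated at 2 h, and MYC, BCL2, MCL1, FADD and PUM2 reached most of their difference between 2 and 8 h; MDM2 is drawn from its brightest probe set, a type that can match several sequences, and some of its other probe sets had the opposite sign.

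Genes kept at least 2-fold from untreated at 8, 16 and 24 h numbered 67 higher and 496 lower. PMAIP1, ATF3, GADD45A, GDF15, IER5 and MDM2 led the higher set, followed by the cytokine gene LIF (signal 34.7 to 108 at 24 h), the metallothionein gene MT1H (136 to 625), the tubulin gene TUBB2A (278 to 820.5) and the folate receptor gene FOLR1 (485 to 1877). PUM2, CDYL, EGR1, MYC, SEC24B, ADNP, FADD, ZC3H4, RSBN1 and CHD1 led the lower set, with FADD, the adaptor that links death receptors to caspases, going from 379 to 44.7. Simulated unchanged arrays against the same untreated array gave at most 3 higher and 5 lower. Their noise was independent between genes and carried no shift between arrays or with brightness. They therefore do not show what unchanged cells would give under the shifts seen here. The sustained counts were 190 and 314 at a common median, 171 and 316 after quantile normalization, 19 and 917 on the normalization-control probe sets, and 8 and 1761 on the hybridization controls. The 8 on the hybridization controls were ATF3, GADD45A, GDF15, H2AJ, HBEGF, IER5, MDM2 and PMAIP1, of which H2AJ and HBEGF were named after their values were seen.

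Comparisons that share no array were set against each other to remove the effect of the shared untreated array. Of the 208 genes higher at 16 h than untreated, 187 (89.9%) were also higher at 8 h than at 2 h, against 40.5% of all genes, and 195 (93.8%) were higher at 24 h than at 2 h, against 35.1%. Of the 982 lower at 16 h, 958 (97.6%) were lower at 8 h than at 2 h and 969 (98.7%) at 24 h than at 2 h, against 59.4% and 64.9% of all genes. Across the 6708 genes, which are not independent replicates, log2 differences of disjoint pairs of arrays correlated at r between 0.64 and 0.81. Differences from the shared untreated array correlated at 0.86 for 8 and 16 h, 0.92 for 16 and 24 h and 0.83 for 8 and 24 h, where the shared array alone gave 0.50. Their covariances were 0.55, 0.74 and 0.60, against 0.0644 from the shared array.

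Because RITA is a p53 activator, direct p53 target genes were one of 24 gene lists fixed before the data were examined. Among 29 measured p53 targets, 8 rose and 2 fell over the course. Over all 6708 genes 691 rose and 1554 fell, and the counts of each list below are to be read against these. PMAIP1 rose by 3.55 log2 units per 24 h (adjusted p = 0.0209 by limma), MDM2 by 2.83 (0.00215), GADD45A by 3.33 (0.0250) and TP53I3, a p53-induced oxidoreductase gene, by 1.47 (0.00317). SUSD6 and the polo-like kinase gene PLK2 fell. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, had signals of 511 untreated and 964, 1435, 1276 and 1366 at the 4 times, and did not pass the straight-line test (adjusted p = 0.0592 by limma). BAX was 2.21-fold higher at 2 h, the DNA-damage phosphatase gene PPM1D was lower (2300.1 untreated, 852 at 8 h, 1271 at 24 h), and FAS, DDB2, XPC and SESN1 were within 1 log2 unit of untreated at each time on the deposited scale. The list's median at 24 h lay 0.35 log2 units above that of all genes, at percentile 96.8 of signal-matched random lists (99.4 at 16 h, and 99.78 at 24 h after quantile normalization), with 7 members at least 2-fold higher and 2 lower. The list's trend was upward against other genes by limma's camera (adjusted p = 0.00748). That call was lost with an estimated correlation (adjusted p = 0.577, limma) and without the 24 h array (adjusted p = 0.0506, limma). The estimated correlation, -0.0291, lay below the preset 0.01, so correlation between the genes does not explain the first loss. With adjustment over the list alone 8 rose and 2 fell, and on the hybridization-control scale the list's 24 h median was -1.03 log2 units from untreated.

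Of 17 pro-apoptotic genes, 4 rose (PMAIP1, BAD, CASP6 and CYCS) and 3 fell: FADD (-3.30 log2 units per 24 h), the initiator caspase gene CASP8 (-1.13) and AIFM1 (-0.66). BAD, CASP6 and CYCS were lower than untreated on the hybridization-control scale. The list as a whole did not pass limma's camera (adjusted p = 0.323), with a 24 h median 0.30 above all genes and 1 member at least 2-fold higher and 2 lower. Median slope and camera direction differed in sign for this list, the integrated stress list and the immediate-early list (negative median, direction up), and for the oxidative-stress and glycolysis lists the mean slope was negative and the median positive. Of 25 genes of survival and growth signalling 11 fell and 1, BIRC5, rose. This list was drawn up with knowledge of published work on RITA, so its direction is not independent evidence. MYC fell by 3.99 log2 units per 24 h (adjusted p = 0.00293 by limma), the anti-apoptotic BCL2 fell by 2.80 (0.00470; signal 594 to 72.4) and MCL1 fell by 1.80 (0.00405; 1904 to 598). The insulin receptor substrate gene IRS1 fell by 2.45, and the phosphoinositide 3-kinase genes PIK3R1 (-1.98) and PIK3CB (-1.92) fell as well. BIRC5, the apoptosis inhibitor survivin, which also acts in mitosis, rose on the deposited scale by 0.74 but was lower than untreated on the hybridization-control scale. The list's median at 24 h lay at -0.36 relative to all genes, at percentile 5.01, or 0.475 after quantile normalization. At 8 h the percentile was 1.27, or 5.15 after quantile normalization, and at 16 h it was 14.5. Of the list's members 8 were at least 2-fold lower at 24 h, and camera gave adjusted p = 0.157 (limma).

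Cell cycle genes of G2 and mitosis fell as a list by limma's camera with the preset correlation, the only list to do so on the deposited scale with hours as they are and all 5 arrays (adjusted p = 0.00158; 0.590 as adjusted p with an estimated correlation). Of 40 members 24 fell and 4 rose, or 27 and 4 when adjusted over the list alone. The kinetochore motor gene CENPE fell by 2.86 log2 units per 24 h (236 to 28.2, below the floor), as did the spindle motor genes KIF23 (-2.58) and KIF11 (-2.30) and the checkpoint kinase gene TTK (-2.30). The list's median at 24 h was -0.62 relative to all genes, below all 10000 random lists, with 17 members at least 2-fold lower and 0 higher. The 34 S-phase genes held 10 that fell and 1 that rose, among them the histone mRNA-binding gene SLBP (-2.05), the DNA polymerase genes POLE2 and POLA1 (-1.67 and -1.34) and the cyclin gene CCNE2 (-1.47). Their median, however, lay at -0.01 relative to all genes and the list did not pass (adjusted p = 0.428, limma camera). Of 27 DNA repair genes 8 fell and 0 rose; BRIP1 fell by 2.09, the helicase gene BLM fell by 1.83 and BARD1 fell by 1.55, and PALB2 went from 192 to 44.2. Their 24 h median was -0.43 relative to all genes (percentile 5.24, or 1.67 after quantile normalization, and 0.28, 17.4 and 0.15 at 2, 8 and 16 h). The list was at adjusted p = 0.0863, limma camera, or 0.0224 on log2(hours + 1). Of 117 zinc finger genes 27 fell, such as ZNF267 (-2.71), and 4 rose, ZNF160 and ZNF721 among them. A similar share of all genes fell, 1554 of 6708. ZNF443 had a signal of 115 untreated and 18.3, below the floor, at 8 h. Adjusted over the list alone, 21 fell and 4 rose, the 24 h median was -0.47 relative to all genes (percentile 0.785), and camera gave adjusted p = 0.0863, or 0.0101 on log2(hours + 1) (limma).

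The luminal identity list, made of breast epithelial transcription factors and keratins, lay -0.51 log2 units from all genes at 24 h, below all 10000 random lists, and 9 of its 14 genes fell while 2 rose. TFAP2A fell by 2.72 log2 units per 24 h, TFAP2C fell by 2.40 (1222 to 236), GATA3 fell by 1.39 (6397 to 2370.4) and ESR1, the estrogen receptor, fell by 1.34 (1134 to 390.5); the median of ESR1's 9 probe sets, most below the floor, had the opposite sign at 24 h. The list did not pass camera (adjusted p = 0.149, limma) but fell by it after quantile normalization (adjusted p = 3.37e-04, limma). Among 23 estrogen-response genes 6 fell and 2 rose: the corepressor gene NRIP1 fell by 2.56, BCL2 fell by 2.80 and the adenylyl cyclase gene ADCY9 fell by 2.59, and RARA was 3.58-fold lower at 24 h. Their median was -0.26 relative to all genes at 2 h (percentile 0.02) and -0.04 at 24 h (percentile 15.1), or -0.44 at 24 h after quantile normalization (percentile 0.79), with adjusted p = 0.812 by limma's camera.

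**Figure D3:**
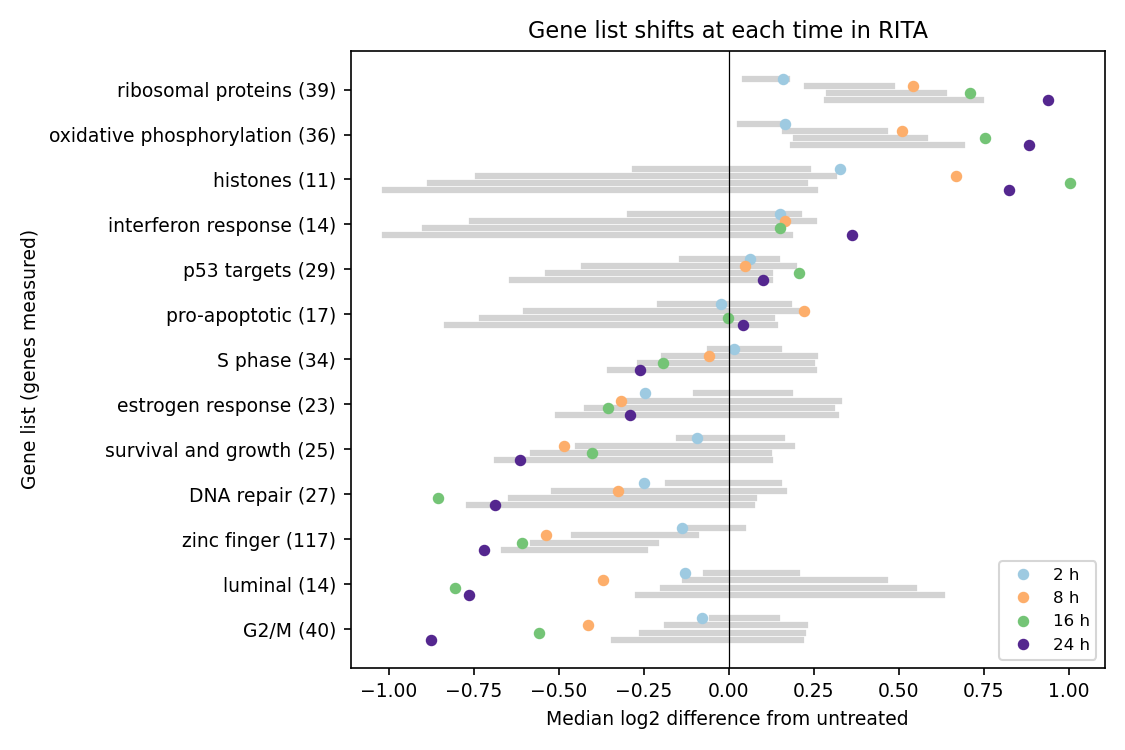
Median log2 difference from untreated (horizontal axis) of 13 gene lists at 2, 8, 16 and 24 h, as points, with the number of genes measured in brackets and grey bars for the central 95% of 10000 random lists of the same size matched on signal. At 24 h the G2/M, luminal and zinc finger lists lay below their bars, and the interferon, histone, ribosomal protein and oxidative phosphorylation lists above theirs, while on the hybridization-control scale these last 4 lay below 0 and after quantile normalization the ribosomal protein list lay within the central 95%.

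Of the stress lists described next, 0 passed limma's camera on the deposited scale. At 2 h the immediate-early list was 0.40 log2 units above all genes, higher than all 10000 random lists, with 6 of 20 genes at least 2-fold higher and 3 lower; by 24 h it lay at 0.21, or -0.12 after quantile normalization. The kinase gene SGK1 went from 17.2, below the floor, to 50.8 at 2 h and 78.1 at 8 h. Over the course 1 of the list rose (ATF3) and 3 fell, EGR1 and MYC among them (adjusted p of the list = 0.712, limma camera). Of 23 genes of the integrated stress and unfolded protein responses 2 rose, ATF3 and NUPR1 (54.5 to 235), and 5 fell; DDIT3 was 2.93-fold higher and the chaperone gene DNAJB9 2.33-fold lower at 24 h (list adjusted p = 0.749, limma camera). The list lay 0.20 above all genes at 2 h (percentile 99.6), with 3 members at least 2-fold higher and 0 lower, and at 0.02 at 24 h (percentile 26.5). Of 13 heat shock genes 6 fell and 3 rose: DNAJB1 fell by 2.68 log2 units per 24 h, BAG3 fell by 1.72, HSPH1 fell by 1.07 and HSPA4L fell by 1.03. The list lay at -0.13 relative to all genes at 24 h (percentile 0.92), a sign that reversed with plain _at probe sets alone and against the 2 h array, and at adjusted p = 0.875 by limma's camera, or 0.0328 (down) after quantile normalization. Among 17 oxidative-stress genes, ferritin light chain FTL and thioredoxin TXN rose by 1.25 and 1.41, and the glutathione synthesis gene GCLC and thioredoxin reductase TXNRD1 fell (-2.07 and -1.44); in all 4 rose and 3 fell (adjusted p = 0.322, limma camera). Of 7 measured NF-κB genes 2 fell, NFKB1 fell by 1.38 and NFKBIE fell by 1.35, and 0 rose (adjusted p = 0.712, limma camera).

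The clearest upward lists by limma's camera were ribosomal proteins (adjusted p = 1.58e-20) and oxidative phosphorylation (adjusted p = 5.75e-13); both calls were lost with an estimated correlation (adjusted p = 0.577 for each). Of 39 ribosomal protein genes 38 rose and 0 fell, or 39 and 0 adjusted over the list alone, RPL34 by 1.42 log2 units per 24 h, and RPS25 among them (5461 to 14131). Of 36 respiratory-chain and ATP synthase genes 25 rose and 1 fell, with UQCRB up 1.65, NDUFB3 1.63, COX7A2 1.43 and COX7B going from 2281 to 6183. At 24 h these lists lay 1.19 and 1.14 above all genes, but on the hybridization-control scale both were lower than untreated (-0.19 and -0.25). Similarly bright genes shared most of the shift: lists drawn from the 20 nearest genes in signal outside both lists had medians of 0.76 and 0.54 log2 units at 24 h, against 0.94 and 0.88 for the lists. After quantile normalization they lay only 0.13 and 0.30 above all genes, at percentiles 90.55 and 99.78 of signal-matched lists, the first inside the central 95%, with camera's adjusted p = 0.0409 and 0.00784 (limma). By contrast 9 of 22 ribosome biogenesis genes fell, including URB2 (-2.38), WDR43 (-2.12) and UTP20 (-1.81), and 2 rose, one being POLR1B, read by a probe set that can match several sequences (list adjusted p = 0.131, limma camera, or 0.0328, down, after quantile normalization). Their 24 h median lay at percentile 6.51, or 0.680 after quantile normalization.

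Among 11 histone genes 5 rose and 0 fell (9 and 0 adjusted over the list alone), with H3C2 going from 8.70, below the floor, to 200.3, H2AC17 up 1.44 log2 units per 24 h and H2AC8 up 1.54. The list passed limma's camera (adjusted p = 4.06e-05; adjusted p = 0.577 with an estimated correlation) and lay 1.08 above all genes at 24 h, although -0.31 from untreated on the hybridization-control scale. Of 14 interferon-response genes 4 rose and 0 fell, IFITM3 by 1.39 (1113 to 3042), while IFI6 was lower at each time. IFITM3 was read by a probe set of the type that can match several sequences and had no other above the floor. The list passed limma's camera (adjusted p = 0.00831), but not with an estimated correlation (adjusted p = 0.577) or without the 24 h array (adjusted p = 0.110). Its median lay -0.77 log2 units from untreated at 24 h on the hybridization-control scale. Of 6 matrix and mesenchymal genes above the floor S100A4 and ACTA2 rose; ACTA2 was lower than untreated at 24 h on the hybridization-control scale, as was the list's median at -0.21 (list adjusted p = 0.00362, limma camera; adjusted p = 0.577 with an estimated correlation). Of 26 proteasome genes 7 rose and 2 fell, PSMB3 up 0.90 and PSMD1 down (-1.29). Camera called the list up (adjusted p = 0.00193, limma; adjusted p = 0.590 with an estimated correlation), its 24 h median lay at percentile 37.3 of signal-matched lists, and its camera direction was down after quantile normalization. PSMB3 was lower than untreated on the hybridization-control scale. The cholesterol list (16 genes, 0 rose, 3 fell, adjusted p = 0.875 by limma's camera) held SQLE, a rate-setting enzyme of sterol synthesis, which fell by 2.76 log2 units per 24 h (1019 to 175), and INSIG1, which fell by 1.30. Of 21 glycolysis and hypoxia genes 5 rose and 5 fell (adjusted p = 0.294, limma camera), with TPI1 up 0.91 and VEGFA down (-0.95); TPI1 was lower than untreated at 24 h on the hybridization-control scale. Of the blood cell markers only CORO1A (signal 31.9 to 54.8) and LCP1 (191 to 101) had mean signals above the floor, too few for a summary. Adjusted over the list alone, 3 integrated stress genes rose and 7 fell, 5 oxidative-stress genes rose and 4 fell, 7 glycolysis genes rose and 5 fell, 2 ribosome biogenesis genes rose and 10 fell, and 9 proteasome genes rose and 2 fell; the remaining lists kept the counts already given.

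Across all 6708 genes, 691 rose and 1554 fell with time at an adjusted p of 0.05 (limma, slope on hours, 3 residual degrees of freedom), and 3081 had an unadjusted p under that level. The lowest adjusted p among genes that fell belonged to TFAP2C, SQLE, DNAJB1, NOP16 (a nucleolar protein gene, -2.35 log2 units per 24 h, SE 0.21), GOLPH3, CNNM4, SLBP, TXNRD1, the mitotic cyclin gene CCNB1 (-1.69, SE 0.17) and BAG3. SLC35E1, HAUS2, ZNF160, NACA4P, ZC3H7B, PGF, PNN, UQCRB, ZNF721 and UQCR11 had the lowest among genes that rose, and of these 10 only UQCR11 was not read by a probe set of the type that can match several sequences. Other probe sets of PNN and SLC35E1 had medians of -0.43 and -0.31 log2 units at 24 h, and those of UQCRB 1.43. TFAP2C fell by 2.40 (SE 0.19, limma adjusted p = 8.13e-04) and UQCR11, a subunit gene of respiratory complex III, rose by 1.76 (SE 0.19, limma adjusted p = 0.00152). The counts depended on single arrays: 434 rose and 841 fell without the untreated array, 387 and 629 without 2 h, 911 and 2089 without 8 h, 381 and 812 without 16 h and 457 and 1028 without 24 h. They depended on scaling as well, with 956 and 1043 at a common median, 688 and 877 after quantile normalization, 392 and 2625 on the normalization-control probe sets and 39 and 5409 on the hybridization controls.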

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

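Control probe sets, which are not among the genes compared, differed from the untreated array at 24 h. The weighing below used tests chosen after the result was seen, except the comparison of the ribosomal protein and oxidative phosphorylation lists with random lists matched in 10 signal groups on the deposited scale, and the planned quantile normalization. Relative to untreated, the hybridization controls stood at 2.19-fold and the poly-A controls at 4.11-fold. The 18S ribosomal RNA probe sets stood at 20.1-fold (3′), 3.04-fold (5′) and 5.74-fold (middle), and a further control transcript at 3.01-fold (middle) and 2.59-fold (5′), while its 3′ probe set, below the floor on each array, stood at 0.221-fold. The ratio of the ACTB 3′ to 5′ signals was 2.21-fold that of untreated (1.47 to 3.25). In addition 34 unnamed _x_at probe sets were at least 2-fold higher at 16 and 24 h but not at 8 h.

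The first pattern weighed was the higher signal of both sets of added transcripts at 16 and 24 h. Less labelled RNA on the later arrays, followed by the authors' scaling, would raise the hybridization controls alone, but the poly-A controls, labelled with the sample, were 2.04 log2 units above untreated at 24 h, beyond their excursion of -0.74 at 2 h, which argues against it as the whole cause. A lower mRNA content per total RNA in treated cells may contribute: the poly-A controls exceeded the hybridization controls by at least 0.578 at both times. That explanation stays open, because the poly-A controls varied by a similar amount at 2 h without a matching difference in the hybridization controls, and an unequal amount of added control RNA cannot be told apart from it on 1 array per time. If it held, the deposited scaling would understate falls and overstate rises.

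The second pattern was the rise of ribosomal protein and oxidative phosphorylation transcripts relative to other genes. Distortion of the brightest signals was argued against as the whole cause by random lists matched in 10 signal groups, among which both lists lay at percentile 100 on the deposited scale. After quantile normalization, which changes signals by their brightness, oxidative phosphorylation lay at percentile 99.78 but ribosomal proteins at 90.55, inside the central 95%, although both lay at 100 among lists of the 20 nearest genes in signal. Members of both lists and other genes with ribosomal protein symbols were left out of the nearest genes. For the brightest members the nearest genes may therefore be dimmer, and percentile 100 there does not offset 90.55. On the deposited scale lists of the 20 nearest genes in signal had medians of 0.76 and 0.54 log2 units against 0.94 and 0.88, so most of the size may be shared with equally bright genes. Truncated labelling on the later arrays stays open, since the poly-A controls' 3′/5′ ratios had a median change of 0.203 log2 units but ranged from -0.50 to 0.37. RNA degradation stays open too: the lower of the ACTB and GAPDH changes was 0.141, that of GAPDH, while ACTB changed by 1.15. A biological effect of RITA on these transcripts also remains possible and was not separated from these.

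The third pattern was that 33 of 114 genes at least 2-fold higher at 16 and 24 h but not at 8 h were read by _x_at probe sets, 28.9% against 7.75% of all genes above the floor. Ribosomal RNA carried into the labelled sample stays open: these genes had a median difference of 0.253 log2 units between 24 and 16 h, with 32 of the 33 higher at 24 h, while the 18S probe sets did not move together (3′ -1.48, 5′ -0.12, middle 0.34). Probes that match other sequences stay open too: the 12 genes with other probe sets above the floor had a median of 1.00 there at 24 h, 6 of them at least 2-fold higher, while ALMS1, LRRFIP1, PNN, SLC35E1 and USP34 had negative medians. A late effect of RITA on repeated or related sequences was not tested.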

How the results depend on the processing

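Scaling on the hybridization controls and leaving out _x_at probe sets were tests chosen after the results were seen; the other alternatives were planned. Of 316 recomputed counts and shares, 180 stayed within 1.5 times the value reported or within its interval and 136 did not. Of 582 recomputed list medians 494 stayed within their spread, 83 moved beyond it and 5 reversed. Of 207 recomputed list tests with limma 60 passed again in the same direction, 119 passed neither before nor after, 16 passed newly (8 of them by fry), 11 no longer passed and 1 no longer passed and reversed. Of 2401 recomputed differences of named genes 1857 stayed, 517 moved and 27 reversed, the last for 16 of 227 pairs of gene and time. A reversal was counted only for the 154 pairs past the 2-fold rule, and for list medians only outside the central 95% of random lists. A further 69 recomputed differences of pairs not past the rule changed sign, 31 of them on the hybridization-control scale, and count as stayed or moved. Except where a sentence says otherwise, the cause was not tested.

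At a common median 58 genes were lower at 2 h, 368 higher and 489 lower at 8 h, 539 and 593 at 16 h and 648 higher at 24 h, with 190 and 314 sustained. Quantile normalization gave 58 lower at 2 h, 337 higher and 491 lower at 8 h, 403 and 569 at 16 h, 523 and 720 at 24 h, and 171 and 316 sustained. On the normalization-control probe sets the pairs were 72 and 1264 at 8 h, 75 and 1639 at 16 h, 115 and 1917 at 24 h, and 19 and 917 sustained. On the hybridization controls 62 were higher at 2 h, and the pairs were 17 and 2265, 19 and 3305, 29 and 3719, with 8 and 1761 sustained. For all of these but quantile normalization, which does not shift all genes alike, the differences follow by construction from the shift of all genes. Genes past the rule at 16 h had the same sign in 8 h against 2 h for 96.2% and in 24 h against 2 h for 97.8% as reported, 97.49% and 98.9% on the normalization-control probe sets, and 99.5% and 99.8% on the hybridization controls.

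A floor at percentile 30 gave 126 higher and 191 lower at 2 h, 336 higher at 8 h, 377 at 16 h, 556 at 24 h and 115 sustained, with agreement of 90.4% and 92.6%. A floor at percentile 70 gave 15 and 15 at 2 h, 89 and 251 at 8 h, 138 and 356 at 16 h, 424 lower at 24 h, and 42 and 123 sustained, with agreement of 98.6% and 99.4%. Without a floor the pairs were 1259 and 1188, 1622 and 2128, 1720 and 2471, 2083 and 2618, and 728 and 1049 sustained, with agreement of 69.7% and 72.4%; signals near background thus limit the size rule, and no statement is made on genes below the floor. Plain _at probe sets alone, which test fewer genes, gave 24 higher at 2 h, then 108 and 480, 97 and 620, 135 and 739, and 36 and 309 sustained. By construction a 1.5-fold rule gave more genes (254 and 502, 757 and 1624, 812 and 1892, 955 and 2114, sustained 394 and 1183; agreement 92.8% and 95.4%) and a 3-fold rule fewer (8 and 5, 16 and 225, 38 and 323, 66 and 437, sustained 6 and 145; agreement 98.1% and 99.4%). Against the 2 h array 48 genes were higher and 371 lower at 8 h, 109 higher at 16 h and 185 at 24 h, and 21 and 222 were sustained.

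For the time trend by limma, leaving out 1 array gave 381 to 911 genes that rose and 629 to 2089 that fell. Without the untreated array the counts were 434 and 841, without 2 h 387 and 629, without 8 h 911 and 2089, without 16 h 381 and 812, and without 24 h 457 and 1028. Quantile normalization gave 877 that fell, the normalization-control probe sets 392 and 2625, and the hybridization controls 39 and 5409. Of the 7 lists up and 1 down by camera, 0 up and 0 down passed with an estimated correlation. Under that setting each list had an adjusted p of 0.577 or above by limma's camera, whatever its estimated correlation. Camera then rests on the 3 residual degrees of freedom, so a call lost there cannot be put down to correlation alone. For the p53 and interferon lists the estimates (-0.0291 and 0.00227) lay below the preset 0.01, so correlation does not explain the loss. The estimates were 0.804 for ribosomal proteins and 0.517 for oxidative phosphorylation. Lists down numbered 3 on log2(hours + 1) (G2/M, DNA repair and zinc finger), 9 by fry (which does not compare with other genes), 4 after quantile normalization (G2/M, luminal identity, heat shock and ribosome biogenesis), and 1 to 2 when 1 array was left out, with 2 without the 2 h, 8 h or 24 h array. Without the 24 h array the p53 and interferon lists no longer passed (limma's adjusted p = 0.0506 and 0.110), while over the p53 list's other alternatives adjusted p ranged from 0.00148 to 0.577 and over the interferon list's from 0.00132 to 0.577. The proteasome list, up as reported, was down after quantile normalization with limma's adjusted p = 0.731; over its alternatives adjusted p ranged from 0.00130 to 0.731.

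Against unmatched random lists 5 lists lay above the central 95% at 2 h, 3 below it at 8 h and 2 below it at 24 h. Plain _at probe sets gave 3 below at 8 h, 3 above at 16 h and 3 above at 24 h, and quantile normalization 8 below at 24 h. The estrogen-response median relative to all genes at 8 h reversed to 0.00857 with the median of probe sets and 0.0747 against the 2 h array. The heat shock median reversed to 0.18 at 8 h and 0.0846 at 24 h with plain _at probe sets, and to 0.0890 at 24 h against the 2 h array.

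Among pairs past the 2-fold rule, on the hybridization-control scale the 24 h differences of ACTA2, ALDOC and RPS27L became -0.0684, -0.0319 and -0.00340 log2 units, as its shift of all genes requires. The other reversals of such pairs came from other probe sets, many of them below the floor. With plain _at probe sets ARID4B was at 1.12 at 2 h, DYRK1A at 2.85 at 16 h and 2.20 at 24 h, GDF15 at -2.04, -1.61 and -1.88 at 8, 16 and 24 h, MDM2 at -1.52 at 8 h and -1.07 at 24 h, SH3BP2 at -0.0393 at 2 h, and SLC35E1 at -0.47 at 16 h and -0.62 at 24 h. With the median of a gene's probe sets DYRK1A was at 0.40 and ESR1 at 0.16 at 24 h, MDM2 at -0.0731 at 8 h, SH3BP2 at -0.0393 at 2 h, and SLC35E1 at -0.47 at 16 h and -0.39 at 24 h. Without _x_at probe sets GDF15 was again at -2.04, -1.61 and -1.88, LTBP4 at -1.07 at 2 h, MDM2 at -0.0731 at 8 h, and SLC35E1 at -0.47 and -0.62.

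No paired analysis was possible because each group had 1 array. A test of a single time against untreated was not possible for the same reason. The trend test missed all simulated changes of 1 log2 unit over 24 h, with 200 changed genes among 6708. On the arrays themselves, where 691 genes rose and 1554 fell, smaller changes did pass. Of 39 ribosomal protein genes 38 rose, with a list median of 0.93 log2 units per 24 h. The simulated recovery therefore does not give the sensitivity on these arrays.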

Other observations

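The order of the times and the timing of the difference were planned tests; the comparison of gene families by shared symbol prefix was chosen after the results were seen. An order of the times and its mirror counted as 1 order, scored by the larger number of genes past limma's trend test. The real order scored 2841 and the highest of the others 2589, that with untreated and 2 h exchanged, so 1 of the 60 distinct orders gave as many. By this score that argues against a chance order, but it cannot tell an effect of RITA from a steady drift of the arrays or of the cultures with time. The hybridization controls also moved steadily, at 0.65, 0.94 and 1.13 log2 units from untreated at 8, 16 and 24 h. Because the hours are unevenly spaced, the score of 2841 belongs to the mirror, and the real order itself gave the 691 and 1554 genes reported, fewer in all than 2589 but more than each of the remaining orders. By rank of time, where an order and its mirror give the same number, the counts were 2692 for the real order and at most 1922 for the others.

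For the 982 genes lower at 16 h than untreated, the share of the median difference between 2 and 24 h that lay between 2 and 8 h was 0.647 (interval 0.616 to 0.673), so on these arrays more of it lay before 8 h than after. For the 208 genes higher at 16 h it was 0.504 (0.458 to 0.561), which leaves open on which side more lay. Both intervals are over genes only and carry no error between arrays or cultures, so neither share is shown to hold beyond these 5 arrays.

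Among 68 families of at least 10 genes with a shared symbol prefix, the 4 lowest median differences at 24 h relative to all genes were those of the DHX helicases (-0.87, 11 genes, percentile 0.640 of signal-matched random lists), ARHGAP (-0.77, 12 genes, percentile 4.48), the histone demethylases KDM (-0.77, 10 genes, percentile 4.86) and the Mediator subunits MED (-0.75, 18 genes, percentile 1.49). The 4 highest were NDUFA (1.32, 10 genes), RPL (1.21, 34 genes), COX (1.16, 15 genes) and RPS (1.09, 29 genes), all of which overlap the ribosomal protein and oxidative phosphorylation lists and their dependence on brightness. Scalings that shift all genes alike leave these relative medians as they are, and quantile normalization was not tried on families.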
